A study of Mus musculus with 8 samples.

How the data were processed

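RNA was measured by sequencing in the whole small intestine of 8 mouse embryos at E15.5, 4 labelled control and 4 labelled Slmap-cKO, with 1 intestine per library per the series design. Per the labels' protocols, RNA was isolated with TRIzol and libraries with the NEBNext Ultra kit. The submitters' processing notes name CASAVA, fastp, HISAT2, featureCounts and DESeq2 1.20.0 and the mouse genome build GRCm39, without saying what each tool did. Their settings, and whether the counting used strand, are not given in the sources used here.

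The authors deposited 1 table of FPKM values (fragments scaled to gene length and library total) for 55681 genes in the 8 libraries, with gene symbols, positions, lengths and biotypes. A further 3 lines of the table were blank in the copy used and are not analysed here. Columns were matched to libraries by their names. Coordinates are those of the table, on GRCm39 per the submitters' processing notes. Reads shared between copies of a gene (Plac9a, Eif3j2, ribosomal protein genes) or between genes that overlap (Gm26064 and Ranbp9) cannot be assigned from these values.

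Since FPKM carries no depth of its own, the value of 1 read was read from the lowest values of each library. FPKM multiplied by gene length and divided by this step gave whole numbers, within a tolerance of 0.01, for 100% of the values above 0, and these were taken as reads per gene. The totals that the authors' FPKM imply were 0.969 to 1.09 times those sums, which means that the deposited values carry a scaling between libraries that the labels do not describe. At these depths a gene at 1 FPKM with a length of 1 kilobase rests on under 20 reads, and intervals on counts cover counting error only.

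The main test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with an intensity trend of the prior variance, for the 14220 genes with a mean of at least 1 FPKM over the 8 libraries. The cKO minus control coefficient was tested 2-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. The labels name no litter, batch or sex, and p-values measure the spread between these embryos. For Slmap and Stk24 an exact 2-sided permutation test over the 70 assignments of the libraries was added, whose smallest possible p is 0.0286.

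Before the data were examined, 43 gene lists were fixed for pathways, cell types and cell states, of which the sex-linked genes served as a check of the libraries. The 40 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01 between genes, and again with a correlation estimated for each list and with fry. Members were also counted with p-values adjusted over the list alone. The rule for genes named in the text was fixed at the same time. It takes Slmap and Stk24, then up to 12 protein-coding genes per direction past the threshold without overlap between groups, or, with under 5 of these, the 10 genes of smallest unadjusted p in that direction. It adds up to 4 called members of each list, or up to 2 members of smallest p where none is called. Any other gene named was chosen after its values were seen.

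The scripts were tested on simulated reads for the same 4 against 4 design, drawn from the real gene means and totals with a negative binomial dispersion of 0.0151. Over 14221 genes, the test recovered 42.2% of 64 genes changed 1.5-fold, 92.3% of 65 changed 2-fold and 98.4% of 63 changed 4-fold, and 4.49% of its calls were unchanged genes. A list shifted by -0.3 on the log2 scale was called with a median of -0.25, and 0 unshifted lists were called. The simulated genes varied independently of each other, and libraries of a group differed only in their totals. In the real libraries the correlation estimated within lists had a median of 0.397. The simulation therefore does not show how often genes or lists are called falsely in these data.

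Alternatives fixed before the data were examined were the pseudocount, the filter, the scaling between libraries, the trend, array quality weights, the label number as a block, a sex axis, protein-coding genes only, each library left out in turn, limma-voom on the recovered reads, a minimum fold change, and other list tests. Added after the data were seen were fits without controls 3 and 4, without these and cKO 2, with the leading residual component, with enterocyte maturation, with a term for libraries numbered 1 and 2 against 3 and 4, with a per-library correction for GC content and gene length, and with scaling by summed reads. GC content came from the longest transcript per gene of GENCODE M21, matched by gene identifier, and was found for 93.5% of the genes of the table. Shares of receptor genes seen carry exact Clopper-Pearson intervals, and medians over genes carry 95% bootstrap intervals from 10000 draws. Libraries were compared in pairs by a chi-square test of their reads and none were duplicates, the smallest value per degree of freedom being 5.98. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.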

Results

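RNA from the whole small intestine was sequenced in 8 mouse embryos at E15.5. The 4 control embryos carried floxed Slmap alleles, and the 4 embryos labelled Slmap-cKO also carried Cre under the Dermo driver (Dermo1 is an older name of Twist2, a gene of mesenchymal cells). Slmap encodes a tail-anchored membrane protein of the STRIPAK phosphatase complex, which restrains the Hippo kinases. The series title pairs it with MST3, the kinase encoded by Stk24, in gut elongation, and the comparison asks which transcripts differed in the gut after the deletion. Reads recovered from the deposited FPKM summed to at least 15663837 per library. Genes with at least 1 read numbered 25832 in control 3 and 25934 in control 4, against 23883 to 24071 in the other 6 libraries. Xist lay at 93.7 to 240.2 FPKM in controls 2 and 4 and in cKO 1, 2 and 3. In controls 1 and 3 and in cKO 4 it lay at 0.0228 to 0.2999 FPKM, with Ddx3y at 14.5 to 20.9 FPKM, so both sexes were present in each group.

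Slmap itself (ENSMUSG00000021870, chromosome 14, 26134323 to 26256086) was not lower in the libraries labelled cKO. It lay at 24.1 ± 0.92 FPKM in the controls and 25.5 ± 1.40 FPKM in the libraries labelled cKO (SD, n = 4 each). The log2 fold change was 0.07 ± 0.07 (SE, limma adjusted p = 0.570; exact permutation p = 0.143), and the 95% interval of the fold was 0.942 to 1.18. The value sums reads over every exon of the gene in whole tissue, and which exon was floxed is not given in the sources used here, so it neither shows nor excludes the deletion. Directions below therefore follow the labels of the libraries. Stk24 (chromosome 14, 121523755 to 121617423) lay at 19.3 ± 2.75 FPKM in the controls and 23.1 ± 1.62 FPKM in the libraries labelled cKO, a log2 fold change of 0.25 ± 0.11 that did not pass (limma adjusted p = 0.2103; exact permutation p = 0.0857).

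**Figure D1:**
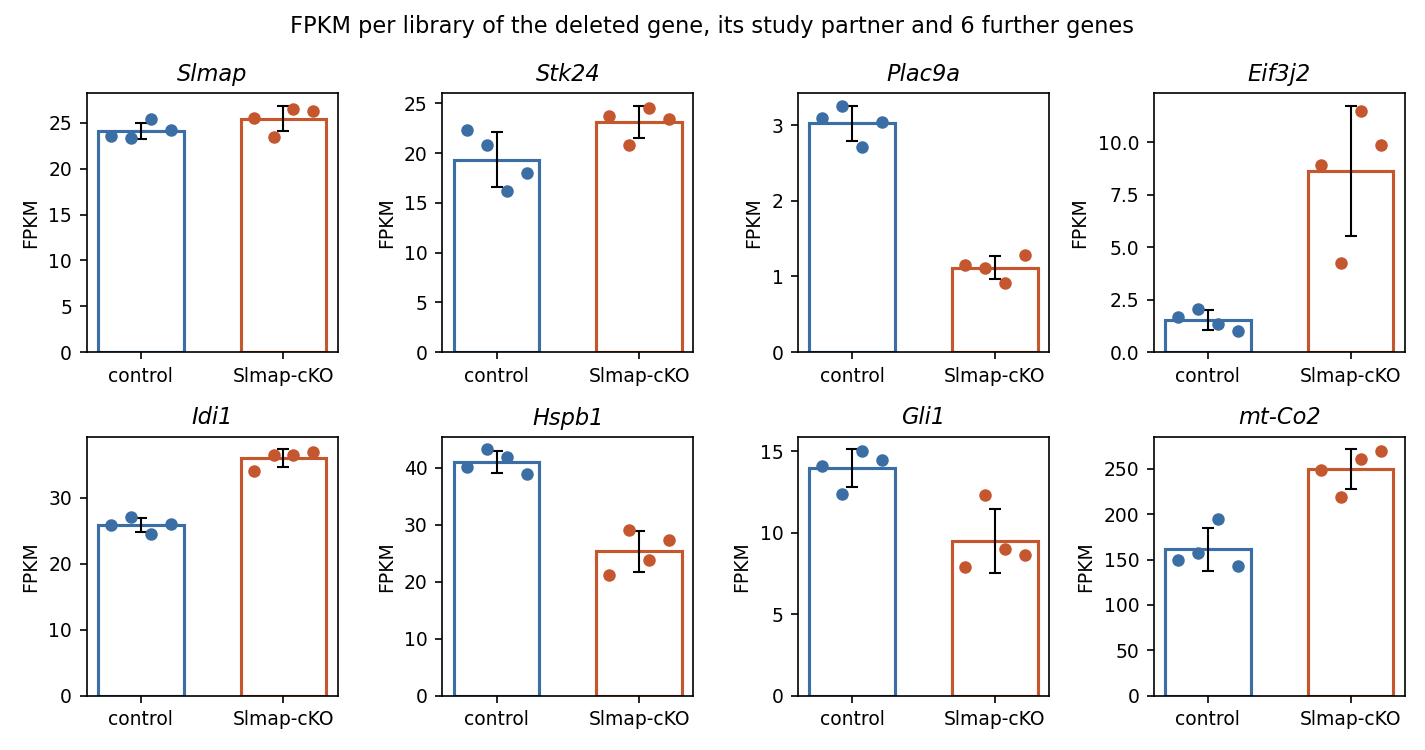
FPKM of 8 genes in each library, with bars at the group mean, error bars of 1 SD (n = 4) and points for single libraries. Slmap lay at 24.1 FPKM in the controls and 25.5 FPKM in the libraries labelled cKO, while Plac9a lay at 3.02 and 1.12 FPKM.

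Of the genes, 2 fell and 0 rose in the libraries labelled cKO out of 14220 tested with limma. Plac9a (ENSMUSG00000095304, chromosome 14, 25887930 to 25903524), which encodes a small secreted protein, fell from 3.02 ± 0.23 to 1.12 ± 0.16 FPKM (SD, n = 4 each), with a log2 fold change of -0.93 ± 0.10 (SE, limma adjusted p = 0.0394). It was lower in 4 of 4 libraries labelled cKO than in every control. The call ended when any library other than cKO 2 was left out (limma adjusted p between 0.0802 and 0.159). The log2 fold change in those fits lay between -0.97 and -0.88. The other gene was Gm26064, a small nuclear RNA gene of 109 bases on chromosome 13 (43579218 to 43579326) that lies inside Ranbp9 on the same strand, so reads there cannot be assigned to either with certainty. It had 3 to 6 reads in each control and 0 in each library labelled cKO, at least 6.38-fold lower against a floor of 3 reads over the group (limma adjusted p = 0.0242). At an unadjusted p under 0.05 there were 1790 genes higher and 1403 lower, against 711 that chance gives in all on average. Genes are correlated, so counts by chance spread widely around that average. Another split of the same 8 libraries into 4 and 4 gave 3350 such genes in all. The balance of directions turned with the scaling, to 1608 higher and 1685 lower with median-ratio scaling and 1184 higher and 2208 lower with summed reads. limma-voom on the recovered reads called 0 genes in either direction, with 1822 higher and 1381 lower at an unadjusted p under 0.05. The values of 2185 genes (15.4%) did not overlap between the groups, against 2.86% by chance on average, with the same limit.

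The 10 protein-coding genes of smallest p in each direction did not pass the threshold, except Plac9a, and each had no overlap between the groups. On the higher side their log2 fold changes were 0.41 to 1.88 with limma adjusted p of 0.0588 to 0.0606. Eif3j2, a copy of a translation initiation factor gene whose reads may be shared with Eif3j1, lay at 1.53 ± 0.46 FPKM in the controls and 8.62 ± 3.11 FPKM in the libraries labelled cKO. Hif1a, the oxygen-regulated transcription factor, lay at 21.9 ± 1.64 and 31.4 ± 1.11 FPKM. Idi1, an enzyme of isoprenoid and cholesterol synthesis, lay at 25.9 ± 1.08 and 36.0 ± 1.31 FPKM. Acsl4, a fatty acid ligase, lay at 5.31 ± 0.51 and 8.24 ± 0.44 FPKM, and Ppp1cb, a catalytic subunit of protein phosphatase 1, at 31.1 ± 0.83 and 41.5 ± 0.75 FPKM. Tinag, Dnttip2, Ppig, Chmp1b and Uba6 made up the rest, with log2 fold changes of 0.45 to 0.51. On the lower side, Ndufa2, a subunit of respiratory complex I, lay at 98.1 ± 5.83 and 55.9 ± 7.64 FPKM. Romo1, a mitochondrial membrane protein gene, lay at 26.3 ± 3.64 and 16.1 ± 0.54 FPKM, and Megf6 at 5.86 ± 0.16 and 2.95 ± 0.65 FPKM. Tex264, Tppp3, Ehbp1l1, Zfp513 and Rex1bd had log2 fold changes of -0.69 to -0.49. After a correction for GC content and length in each library, the adjusted p of the genes other than Plac9a lay between 0.1302 and 0.386 (limma). Hif1a then had a log2 fold change of 0.33, Idi1 of 0.31, Ppp1cb of 0.23 and Ppig of 0.25, against 0.50, 0.46, 0.41 and 0.45 before. Tex264 had -0.28 and Zfp513 -0.27, against -0.52 and -0.51 before, while Eif3j2 had 1.73 and Ndufa2 -0.69.

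These counts rested on which libraries entered the fit and on the terms in it. Without cKO 2 limma called 792 genes higher and 590 lower. With array quality weights, which let each library count by its fit to the model, it called 1180 higher and 1029 lower. In both fits 1282 genes were called, in the same direction. The weights counted cKO 2 least, at 0.329, so the 2 fits are alike and their overlap is not independent support. With every library kept and a term for numbers 1 and 2 against 3 and 4, limma called 615 higher and 484 lower. The first principal component held 36.3% of the variance and ran from cKO 2 at -27.5 to controls 4 and 3 at 24.3 and 33.3, with controls 1 and 2 at -17.7 and -19.2. The second held 23.3% and set the 4 controls (12.4 to 15.8) apart from cKO 1, 3 and 4 (-24.6 to -14.98), with cKO 2 at 6.16. Across the tested genes, which are not independent replicates, the log2 fold change correlated with GC content (Spearman rho = -0.558). The median log2 fold change was 0.16 in the lowest of 4 equal groups of genes by GC content and -0.17 in the highest. A correction for GC content and length in each library brought the genes at an unadjusted p under 0.05 down to 974 higher and 694 lower. It called 1 gene in each direction, the lower one being Gm26064 (limma adjusted p = 0.00497). Plac9a stood at -0.82 ± 0.09 (SE, against -0.93 before) and just missed the threshold, so its call ended (limma adjusted p = 0.05003).

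**Figure D2:**
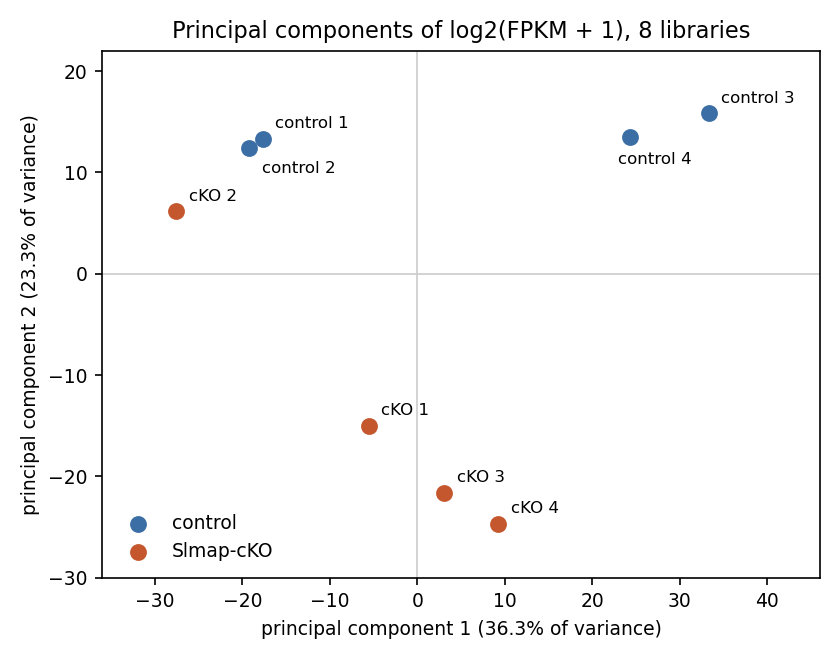
The 8 libraries on the first 2 principal components of log2(FPKM + 1), with the share of variance on each axis. Controls 3 and 4 lie at 33.3 and 24.3 on the first component, and cKO 2 lies at 6.16 on the second, above the other libraries labelled cKO.

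**Figure D3:**
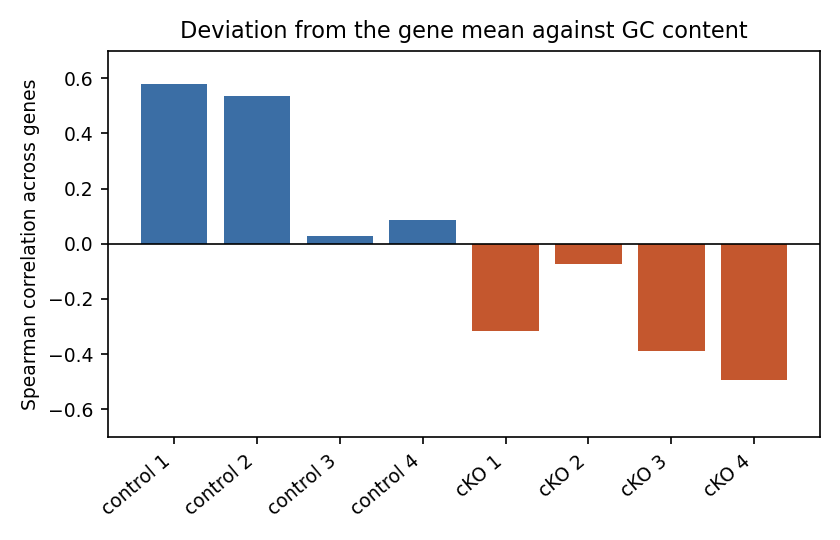
Spearman correlation across genes between GC content and the deviation of each library from the gene mean, 1 bar per library. The values run from 0.579 in control 1 and 0.0291 in control 3 to -0.0727 in cKO 2 and -0.494 in cKO 4.

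Of the 40 gene lists tested, camera called 6 higher and 7 lower in the libraries labelled cKO. With an estimated correlation, and with fry, 0 lists were called. Over all genes tested, 0 list members passed.

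Smooth muscle contractile genes fell as a list, which held genes of contractile and filament proteins and also regulators such as Srf and Myocd. Of 27 tested members 23 had a log2 fold change below 0, with a median of -0.26 (camera adjusted p = 7.99e-06; adjusted p = 0.910 with an estimated correlation). Adjusted over the list alone, 8 members were lower and 0 higher. Hspb1, a small heat shock protein gene, lay at 41.1 ± 1.88 FPKM in the controls and 25.3 ± 3.58 FPKM in the libraries labelled cKO, and Myl6, a myosin light chain gene of smooth and non-muscle cells, at 164.9 ± 25.6 and 105.0 ± 18.3 FPKM. The other 6, seen after the test, were Des, Smtn, Lmod1, Myl9, Synm and Csrp1. Acta2, Actg2, Myh11, Tagln and Cnn1, also in the list, were not among the 8. In mean deviation from the gene mean, cKO 2 scored 0.09 for this list, above controls 3 and 4 at 0.03 and 0.02. The median was -0.21 after the GC and length correction (camera adjusted p = 4.38e-07) and -0.44 without controls 3 and 4 (camera adjusted p = 3.95e-07).

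Mesothelial markers, genes of the outer lining of the gut, fell too, with all 10 tested members below 0 and a median of -0.54 (camera adjusted p = 1.12e-05; adjusted p = 0.828 with an estimated correlation). Of these, 7 were lower when adjusted over the list alone. Rspo1, a secreted Wnt potentiator, lay at 6.97 ± 1.78 FPKM in the controls and 3.53 ± 0.47 FPKM in the libraries labelled cKO, and Lrrn4 at 6.87 ± 2.35 and 3.05 ± 0.53 FPKM. Controls 3 and 4 scored 0.55 and 0.40 for this list and controls 1 and 2 both 0.08, and without controls 3 and 4 the median was -0.33 (camera adjusted p = 0.000723). The extracellular matrix list fell with a median of -0.16 over 32 genes (camera adjusted p = 0.00597; adjusted p = 0.910 with an estimated correlation). The median was -0.26 without cKO 2 and -0.41 without controls 3 and 4. The groups overlapped in the scores for the matrix list. Controls 1 and 2 scored 0.35 and 0.31, but controls 3 and 4 scored -0.11 and -0.16. Of the libraries labelled cKO, cKO 1 and 2 scored 0.06 and 0.17, and cKO 3 and 4 scored -0.34 and -0.28. Fbln2, a matrix glycoprotein gene, was its only member past the threshold when adjusted over the list alone, at 8.69 ± 0.93 and 4.51 ± 1.16 FPKM, and Loxl1 lay at 9.87 ± 1.15 and 6.35 ± 1.74 FPKM. Hedgehog pathway genes fell with a median of -0.16 over 18 genes (camera adjusted p = 0.00597; adjusted p = 0.910 with an estimated correlation). This call ended after the GC and length correction, where the median was -0.12 (camera adjusted p = 0.0878). Without controls 3 and 4 it was -0.29 (camera adjusted p = 0.000413). Gli1, a transcription factor that Hedgehog signalling switches on, lay at 14.0 ± 1.15 and 9.47 ± 1.96 FPKM and was the only member past the threshold when adjusted over the list alone, and the receptor gene Boc lay at 6.35 ± 0.31 and 4.56 ± 0.90 FPKM. After the GC and length correction Gli1 had a log2 fold change of -0.32 (limma adjusted p = 0.397), against -0.53 before.

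Intestinal HOX genes, which mark position along the gut, fell with a median of -0.31 over 17 tested genes (camera adjusted p = 0.00597; adjusted p = 0.910 with an estimated correlation). In this list cKO 2 scored 0.28, above all 4 controls (0.03 to 0.23), and cKO 1, 3 and 4 scored -0.26 to -0.24. Hoxa3 lay at 3.54 ± 0.23 FPKM in the controls and 2.51 ± 0.28 FPKM in the libraries labelled cKO and passed when adjusted over the list alone, and Hoxc4 lay at 6.26 ± 0.28 and 4.66 ± 1.19 FPKM. Immune cell markers fell with a median of -0.24 over 12 genes (camera adjusted p = 0.00597; adjusted p = 0.910 with an estimated correlation), of which 3 passed over the list alone. The median was -0.11 after the GC and length correction (camera adjusted p = 0.0140). The 3 were Tyrobp, the complement gene C1qa at 13.9 ± 1.27 and 9.499 ± 2.31 FPKM, and the macrophage lysozyme gene Lyz2 at 12.5 ± 1.39 and 9.71 ± 0.79 FPKM. Cytosolic ribosomal protein genes fell with a median of -0.20, 47 of 58 lying below 0 (camera adjusted p = 1.41e-05; adjusted p = 0.910 with an estimated correlation). After the GC and length correction the ribosomal median was -0.13 (camera adjusted p = 0.000325). Rpl38 (250.4 ± 2.97 and 147.1 ± 37.4 FPKM) was lower when adjusted over the list alone, and reads of these genes can be shared with their many pseudogenes.

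On the higher side, all 28 G2 and mitosis genes had a log2 fold change above 0, with a median of 0.27 (camera adjusted p = 1.85e-07; adjusted p = 0.910 with an estimated correlation). Of these, 10 were higher when adjusted over the list alone. Cenpe, a kinetochore motor gene, lay at 11.3 ± 1.06 FPKM in the controls and 14.98 ± 0.71 FPKM in the libraries labelled cKO, and Hmmr, a spindle protein gene, at 14.4 ± 1.72 and 19.8 ± 1.29 FPKM. Controls 3 and 4 scored -0.39 and -0.27 for this list, while controls 1 and 2 scored 0.06 and 0.05 and the libraries labelled cKO 0.06 to 0.22. Without controls 3 and 4 the call ended, with a median of 0.10 (camera adjusted p = 0.0544). The G1 to S and replication list rose with a median of 0.23 over 30 genes (camera adjusted p = 0.00597; adjusted p = 0.910 with an estimated correlation). Pola1 lay at 7.20 ± 1.62 and 10.3 ± 0.59 FPKM and Ccne2 had a log2 fold change of 0.27, and 0 members passed over the list alone. Without controls 3 and 4 its median was -0.02 (camera adjusted p = 0.714). The call ended too without cKO 2 (median 0.16, camera adjusted p = 0.188) and with array quality weights (median 0.06, camera adjusted p = 0.484).

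Mitochondrially encoded genes rose, all 15 lying above 0 with a median of 0.52 (camera adjusted p = 5.48e-06; adjusted p = 0.910 with an estimated correlation). Of these, 8 were higher when adjusted over the list alone. With quantile normalization the median was 0.27 (camera adjusted p = 0.00162). mt-Co2, a subunit of cytochrome oxidase, lay at 161.2 ± 23.4 and 249.5 ± 22.1 FPKM, and mt-Atp8 at 2.37 ± 1.38 and 7.78 ± 2.18 FPKM. Mitochondrial protein-coding genes took 2.21% ± 0.27 of the reads of control libraries and 2.85% ± 0.32 of those labelled cKO (SD, n = 4 each). Nuclear oxidative phosphorylation genes were not called, with a median of -0.05 (camera adjusted p = 0.232), but were called lower with quantile normalization (camera adjusted p = 0.0422). Over the list alone 4 of its genes passed, Ndufa2, Ndufa1 and Ndufb8 (16.9 ± 1.23 and 13.4 ± 0.45 FPKM) lower and Tfam, a factor for transcribing the mitochondrial genome, higher. Cholesterol synthesis genes rose with a median of 0.14 over 24 genes (camera adjusted p = 0.0143; adjusted p = 0.910 with an estimated correlation). Idi1 and Hmgcs1 (59.0 ± 7.60 and 85.2 ± 3.94 FPKM), which encodes the enzyme that makes HMG-CoA, passed over the list alone. The call ended without controls 3 and 4 (median 0.12, camera adjusted p = 0.144) and with quantile normalization (camera adjusted p = 0.131). Without cKO 2 the median was 0.22 (camera adjusted p = 0.00245). Epithelial markers rose with a median of 0.14 over 26 genes (camera adjusted p = 0.0361; adjusted p = 0.910 with an estimated correlation). Esrp1 lay at 10.7 ± 2.34 and 15.7 ± 1.10 FPKM and Klf5 at 30.3 ± 5.65 and 39.2 ± 3.83 FPKM. The epithelial call ended without controls 3 and 4 (median -0.02, camera adjusted p = 0.911) and with quantile normalization (camera adjusted p = 0.0959). It was 0.25 in median both without cKO 2 (camera adjusted p = 0.00116) and after the GC and length correction (camera adjusted p = 6.29e-07).

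**Figure D4:**
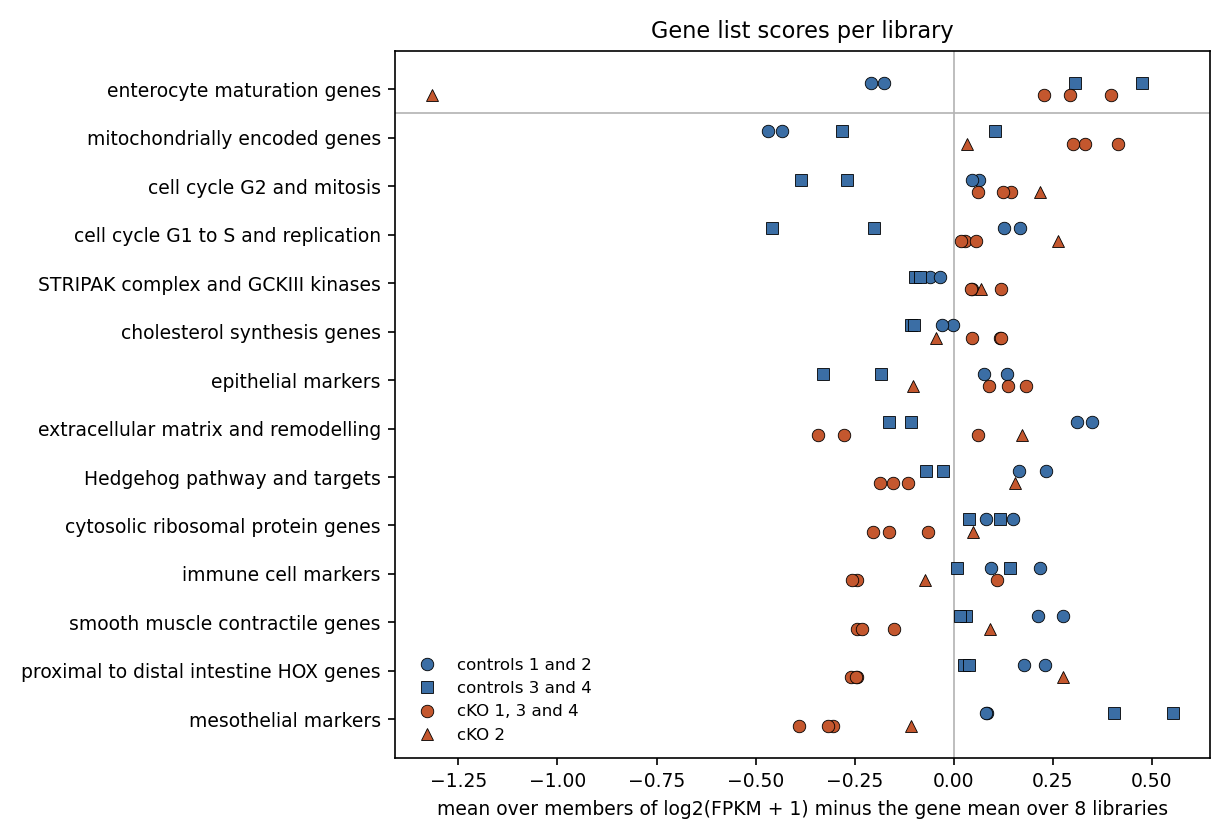
Score of each library for the 13 called lists and for enterocyte maturation genes, as the mean over list members of log2(FPKM + 1) minus the gene mean over 8 libraries. Controls 3 and 4 (squares) lie at -0.39 and -0.27 for G2 and mitosis, and cKO 2 (triangle) lies at -1.32 for enterocyte maturation.

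For the pathways around Slmap, the STRIPAK and GCKIII kinase list rose with a median of 0.17 over 18 genes, Slmap and Stk24 among them (camera adjusted p = 0.0382; adjusted p = 0.828 with an estimated correlation). Strn, a scaffold of the complex, lay at 7.61 ± 0.43 FPKM in the controls and 10.03 ± 1.46 FPKM in the libraries labelled cKO, and Ppp2ca, its phosphatase catalytic subunit, at 38.9 ± 3.25 and 46.2 ± 0.95 FPKM. The call ended with the median about kept without cKO 2 (median 0.16, camera adjusted p = 0.0721) and with array quality weights (median 0.16, camera adjusted p = 0.0662). It ended with a lower median with quantile normalization (median 0.11, camera adjusted p = 0.135), without controls 3 and 4 (median 0.10, camera adjusted p = 0.106), and after the GC and length correction (median 0.04, camera adjusted p = 0.353). Hippo pathway components were not called, with a median of 0.04 (camera adjusted p = 0.462). Adjusted over the list alone, 3 were higher, the kinase genes Stk3 (6.35 ± 0.42 and 8.36 ± 0.40 FPKM) and Stk4 and their cofactor Mob1a (45.1 ± 1.58 and 56.6 ± 2.77 FPKM), and 2 were lower, Taok2 and Tead3. After the GC and length correction Stk3 had a log2 fold change of 0.155 (limma adjusted p = 0.482) and Mob1a of 0.175 (limma adjusted p = 0.391), against 0.35 and 0.32 before. YAP/TAZ target genes had a median of -0.11 and were not called (camera adjusted p = 0.0869), but were called lower without cKO 2 (median -0.15, camera adjusted p = 0.0229) and without controls 3 and 4 (median -0.12, camera adjusted p = 0.0291). Arhgef17 lay at 14.2 ± 1.81 and 11.3 ± 1.75 FPKM and Ptpn14 at 5.46 ± 0.23 and 4.80 ± 0.17 FPKM. PI3K-AKT-mTOR components (median 0.06, camera adjusted p = 0.465) and FOXO targets (median 0.01, camera adjusted p = 0.977) were not called. Gsk3b lay at 13.4 ± 1.08 and 16.6 ± 0.84 FPKM and Sesn3 at 7.51 ± 1.00 and 9.84 ± 1.12 FPKM. Non-canonical Wnt genes (median -0.07, camera adjusted p = 0.462), canonical Wnt targets (median 0.02, camera adjusted p = 0.949), BMP and TGF-beta genes (median -0.09, camera adjusted p = 0.443) and FGF and ERK targets (median -0.04, camera adjusted p = 0.523) were not called. The non-canonical Wnt list was called lower without controls 3 and 4 (median -0.17, camera adjusted p = 0.0405) and with array quality weights (camera adjusted p = 0.0361). After the GC and length correction its median was -0.0013 (camera adjusted p = 0.943). Canonical Wnt targets were called lower only without controls 3 and 4 and cKO 2 (median -0.17, camera adjusted p = 0.00534). Nkd1, a Wnt feedback gene, lay at 8.50 ± 1.34 and 5.61 ± 1.01 FPKM. Id1 and Id2, targets of BMP signalling, went apart, Id1 from 47.1 ± 1.201 to 38.5 ± 1.51 FPKM and Id2 from 47.8 ± 1.67 to 60.8 ± 5.05 FPKM. Both were past the threshold when adjusted over their list alone and, over all genes, with array quality weights (limma adjusted p = 0.0205 and 0.0195).

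Markers of further cell types were not called. Enterocyte maturation genes had a median of -0.14 (camera adjusted p = 0.462) and wide spread within the groups, with Fabp1 at 648.6 ± 284 and 353.1 ± 195 FPKM. Without cKO 2 this list was called higher with a median of 0.23 (camera adjusted p = 0.0111). Enteric neuron markers (median -0.03, camera adjusted p = 0.786), enteric glia markers (median -0.12, camera adjusted p = 0.292), interstitial cells of Cajal (median 0.09, camera adjusted p = 0.786), vessel endothelium (median -0.07, camera adjusted p = 0.767) and lymphatic endothelium (median -0.12, camera adjusted p = 0.336) did not pass. Neuron and glia medians were -0.23 and -0.30 without cKO 2 (camera adjusted p = 0.0865 and 0.0857). The glia median was 0.03 without controls 3 and 4 (camera adjusted p = 0.420). Without controls 3 and 4 the vessel list was called lower (median -0.30, camera adjusted p = 0.000296) and the neuron list had a median of -0.32 (camera adjusted p = 0.146), and with array quality weights the neuron list was called lower (camera adjusted p = 0.0475). After the GC and length correction the vessel median was 0.11 (camera adjusted p = 0.597) and the neuron median -0.0004 (camera adjusted p = 0.689). In the neuron list 2 named genes went apart. Ednrb, a receptor gene of enteric progenitors, lay at 54.9 ± 3.18 and 69.9 ± 1.95 FPKM, and Hand2 at 19.5 ± 2.09 and 12.5 ± 4.80 FPKM. Over all genes neither passed (limma adjusted p = 0.0758 and 0.124), but both did with array quality weights (limma adjusted p = 0.0194 and 0.0165). Sox10 lay at 6.04 ± 0.84 and 4.54 ± 1.30 FPKM, and Kitl, the ligand of Kit, at 21.6 ± 3.41 and 28.9 ± 4.37 FPKM. The mesenchymal fibroblast list was not called (median -0.21, camera adjusted p = 0.0863), but was called lower without cKO 2 (median -0.32, camera adjusted p = 0.00245), without controls 3 and 4 (median -0.41, camera adjusted p = 0.00198) and after the GC and length correction (median -0.13, camera adjusted p = 0.0127). Dpt, a matrix gene of fibroblasts, passed over the list alone at 4.69 ± 0.80 and 2.18 ± 0.59 FPKM. Secretory epithelial lineages (median -0.02, camera adjusted p = 0.919) held 2 members past the threshold over the list alone, Neurod1 at 1.36 ± 0.22 and 2.09 ± 0.12 FPKM and Atoh1 at 2.59 ± 0.32 and 3.75 ± 0.48 FPKM. Pancreatic markers (median -0.56, camera adjusted p = 0.0666), hepatocyte markers (median 0.31, camera adjusted p = 0.0869) and erythroid genes (median 0.30, camera adjusted p = 0.299) were not called, but hepatocyte markers were called higher without cKO 2 (median 0.42, camera adjusted p = 0.0421). The erythroid median was 0.07 without cKO 2, and it turned to -0.20 with array quality weights and -0.36 without controls 3 and 4, uncalled in each. Of the skeletal muscle markers 3 were tested and of the stomach and oesophagus markers 0, too few for a test.

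The lists of cell state not described above were not called either. p53 targets and apoptosis genes had a median of 0.02 (camera adjusted p = 0.767). Among them were the death effector genes Bax at 31.9 ± 1.57 and 24.0 ± 1.72 FPKM and Bbc3 at 2.77 ± 0.37 and 1.62 ± 0.25 FPKM, both lower when adjusted over the list alone. Cell cycle inhibitors had a median of -0.05 (camera adjusted p = 0.977), with Rbl1 at 10.4 ± 0.84 and 13.7 ± 0.66 FPKM and Cdkn2d at 10.4 ± 1.07 and 7.51 ± 0.81 FPKM. Immediate early genes (median -0.19, camera adjusted p = 0.0617), hypoxia and glycolysis (median 0.05, camera adjusted p = 0.820), interferon-stimulated genes (median 0.07 but mean -0.08, camera adjusted p = 0.631), the unfolded protein response (median 0.05, camera adjusted p = 0.786) and actin cytoskeleton regulators (median 0.01, camera adjusted p = 0.534) did not pass. Immediate early genes were called lower without cKO 2 (camera adjusted p = 0.0470) and with array quality weights (camera adjusted p = 0.0475). In the actin list Rock1 (5.599 ± 0.40 and 7.32 ± 0.59 FPKM) and Cdc42 (150.4 ± 12.9 and 195.1 ± 11.6 FPKM), regulators of cell contraction and polarity, were among 4 members higher when adjusted over the list alone.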

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

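For each named gene, list score and library total, the libraries of a group were searched for 1 value far from the other 3 by Dixon's test, and 20 of 294 groups were picked out where chance alone gives 14.7. Of these 20, 9 lie in cKO 2 and 5 in control 3. The blood test was chosen after the results were seen, in place of a test on globins whose value lay within its spread of its bound. The conditions on expression and globins that left the stage test undecided were added then.

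In cKO 2 the score for enterocyte maturation genes was -1.32, against 0.23 to 0.40 in the other libraries labelled cKO, with Apoa1 at 170.3 FPKM against 457.4 to 519.4. The gap to the other libraries labelled cKO had a median of -1.46 log2 (95% bootstrap interval over genes -1.73 to -1.22), and 26 of 27 genes were lowest of all 8 libraries there. A lower share of epithelium would move epithelial markers as far, and their median was -0.28 (-0.41 to -0.22), while RNA from blood would dilute all genes alike, and the median over all tested genes was 0.0104, so neither accounts for the pattern alone. An earlier stage of this embryo stays open, since 6 genes that decline with fetal age had a median of 0.0309 (-0.14 to 0.13), below the 0.24 of control 1 and so against it by the bound set beforehand, but that bound was unfit, as Lin28a and Lin28b lay near the floor and the rest went both ways. The embryonic globins Hbb-y and Hba-x were on average 2.02 log2 higher than in the other libraries labelled cKO and adult globins 1.02. A further embryonic globin, Hbb-bh1, was 0.35 log2 higher but lay near the floor, at 0.36 FPKM in cKO 2. Litter and the length of gut sampled stay untested.

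Controls 3 and 4 detected more genes than the other 6 libraries. Deeper sequencing does not account for it, since after thinning to equal reads both still detected at least 1871 genes more than any other library. Genomic DNA would give reads in receptor genes that the gut does not use, and of 1504 such genes 64 had a read in control 3 and 60 (3.99%, exact 95% interval 3.06 to 5.11) in control 4, against 41 to 52 elsewhere (up to 3.46%, 2.59 to 4.51). The intervals overlap, which by the bound set beforehand goes against genomic DNA, but the counts are few, and unconfirmed gene models (0.160% and 0.145% of reads against 0.0688% to 0.109%) and small RNA genes (0.0217% and 0.0198% against 0.00771% to 0.0127%) were also higher in both, so it stays open. No biological explanation was tested, since the labels do not set these embryos apart.

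The other values picked out are given without explanation. In cKO 2, the score for HOX genes was 0.28 (others of the group -0.26 to -0.24), for G1 to S genes 0.26 (0.02 to 0.06) and for cell cycle inhibitors -0.14 (0.04 to 0.06). Also in cKO 2, Arhgef17 lay at 13.9 FPKM (10.3 to 10.6), Sox10 at 6.48 (3.73 to 3.98), Hoxc4 at 6.43 (3.88 to 4.21) and Cdkn2d at 8.73 (7.04 to 7.19). In control 3, Dnttip2 lay at 20.4 FPKM (22.5 to 22.9), Emcn at 1.57 (2.36 to 2.52), Serpina1a at 0.160 (2.49 to 2.60), Serpina1b at 1.74 (7.44 to 9.32) and Rock1 at 6.20 (5.36 to 5.44). In control 1, Chmp1b lay at 11.3 FPKM (9.92 to 10.1) and Hoxc4 at 6.68 (6.08 to 6.16), and in control 4 Strn lay at 6.97 FPKM (7.77 to 7.87). In cKO 1, Socs3 lay at 3.98 FPKM (5.16 to 5.42), and in cKO 3 Tinag lay at 5.37 FPKM (5.84 to 5.87) and 24071 genes were detected (23976 to 23988).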

How the results depend on the processing

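The fits without controls 3 and 4, with covariates other than sex, with GC and length correction and with summed reads were chosen after the data were seen. Of the named-gene values over all alternatives, 2117 kept direction and side of the threshold, 471 became stronger, 14 weaker and 5 reversed. Genes higher and lower (0 and 2) became 0 and 0 with a pseudocount of 0.1, no filter, a sex axis or voom, 0 and 1 with protein-coding genes only or a log2 fold change of at least 1, 22 and 23 at a mean of at least 5 FPKM, 12 and 19 with median-ratio scaling, 14 and 20 with quantile normalization, and 1180 and 1029 with array weights. With 1 library left out they ran from 0 to 792 higher and 0 to 590 lower, the highest without cKO 2. They were 1 and 2 without controls 3 and 4, 2171 and 2069 without these and cKO 2, 1269 and 945 with the leading residual component, 819 and 731 with enterocyte maturation, 615 and 484 with numbers 1 and 2 against 3 and 4, 1 and 1 after GC and length correction, and 5 and 23 with summed reads. The cause was not tested.

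Lists higher and lower (6 and 7) became 0 and 0 with an estimated correlation or fry, 3 and 8 at 5 FPKM, 3 and 9 with quantile normalization, 4 and 12 with weights, 1 and 11 without controls 3 and 4, and 2 and 13 without these and cKO 2. Reversed in log2 fold change without controls 3 and 4 were Axin2 (-0.0746), the epithelial median (-0.0184) and the G1 to S median (-0.0181). Without cKO 2 as well, Axin2 was -0.115, Fabp1 0.0945, Apoa1 0.129 and the G1 to S median -0.0883. The Slmap log2 fold change was -0.0302 after GC and length correction. The label numbers do not pair the libraries (same-number correlations 0.07 to 0.33, 3 of 8 best with their own number), and blocking on them gave 0 genes higher and 0 lower, with 7 lists higher and 9 lower, pancreatic (camera adjusted p = 0.0158) and hepatocyte markers (0.0453) among them. Depth limits genes near 1 FPKM.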

Other observations

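The tests without controls 3 and 4, the Twist2 test, the term for label numbers and the balanced splits were chosen after the results were seen, as were the interval of the difference of medians and the condition on the interval in the Plac9a test.

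Ranbp9, which holds Gm26064, lay at 9.73 to 9.90 FPKM in the controls and 11.4 to 12.2 in the libraries labelled cKO. Next to Plac9a on chromosome 14, Tmem254a had a log2 fold change of -0.62 (limma adjusted p = 0.0758) and Duxbl1 of -0.53 (limma adjusted p = 0.104), both lower without overlap between groups and both noticed after their values were seen.

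The smooth muscle list fell and the G2 and mitosis list rose. GC content and gene length do not account for either as a whole, since medians after correction were -0.21 and 0.20 and camera with its preset correlation still called both (with an estimated correlation neither is called before correction, adjusted p = 0.910), and enterocyte maturation does not either, with medians of -0.31 and 0.23 with it as a covariate. A higher share of epithelium would lower other non-epithelial markers alike, but neuron and vessel endothelium markers had a median of -0.0505 (95% bootstrap interval -0.135 to 0.0786) against -0.431 to -0.137 for smooth muscle. This meets the bound set against it beforehand, but narrowly, at -0.135 against -0.137. The intervals resample genes, which are correlated, and not embryos, so the share of epithelium is not settled. The medians of the neuron and vessel markers and of smooth muscle differed by 0.20 (0.06 to 0.39). Without controls 3 and 4 these medians, -0.32 and -0.44, differed by 0.12 (-0.06 to 0.28), and fibroblast and matrix lists had medians of -0.41, so there the fall was not particular to smooth muscle, yet epithelial markers did not rise (median -0.0184, -0.07 to 0.06), and the mitosis median was 0.10 and its call ended, which is consistent with controls 3 and 4 carrying much of the mitosis result. A lower level of smooth muscle transcripts in the mutant gut is a hypothesis that stays open, found and tested on the same libraries.

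The libraries can be split into groups of 4 and 4 in 35 ways. As many genes were called in 5 splits, the real one included (up to 247 in another), as many had an unadjusted p under 0.05 in 2 splits (up to 3350), and as many lists were called in 16 splits (up to 22). The split with 247 genes sets the libraries numbered 1 and 2 against those numbered 3 and 4 in both groups, and a term for it gave 615 genes higher and 484 lower. Among the 18 splits balanced over these numbers the real one had the most genes at an unadjusted p under 0.05 (1 split as large, the next at 1651), while as many genes were called in 3 and as many lists in 5. With 18 splits the smallest share is 5.56%, so chance is not excluded. The only split above the real one in the unadjusted count, at 3350, was the one by these numbers. The balanced splits, chosen after that was seen, leave it out. The first place of the real split among them was therefore fixed in advance and is no support. What the numbers stand for is not given in the labels.

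A change around the Slmap locus was tested as a hypothesis for Plac9a, which ends 230.8 kb before Slmap. The other 16 genes within 1 Mb of Slmap had a median absolute log2 fold change of 0.20 (95% bootstrap interval 0.16 to 0.26), at the 83.1 percentile of random sets, with the 95th percentile inside that interval, so the test leaves it open. For Eif3j2, reads moved from its copy Eif3j1 would lower the latter, which instead was 11.9 RPM higher. A shift of reads with Eif3j1 otherwise unchanged therefore does not account for the rise of Eif3j2. A rise of Eif3j1 could hide such a shift, and reads of the copies cannot be assigned here, so shared reads stay open. If the Cre sits in the Twist2 locus, Twist2 reads could fall with the allele, and they lay at 0.393 FPKM in controls and 0.224 in libraries labelled cKO (exact permutation p = 0.0571), which does not decide it.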
